A study of Caenorhabditis elegans with 2 samples.

How the data were processed

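Whole C. elegans L4 larvae of a strain with a tagged nhr-42 transgene were profiled by chromatin immunoprecipitation with an antibody against GFP, in 2 biological replicates, per the labels. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. A possible control experiment is named in the labels and was not analysed here. Both replicates form 1 group, so no test between groups was made, and p-values compare peaks with random positions, with other peaks or with other genes.

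The authors deposited 8 peak lists on build ce11, per the file headers and labels. A thresholded list and a longer ranked list exist for each replicate, and 2 of each kind exist for the series. Per the descriptions that accompany the files, the replicate lists were made from the alignments of that replicate alone and the series lists from those of both. The peak caller, aligner and their versions are not given in the sources used here. The score of each peak in the deposited lists is a scaled irreproducible discovery rate (IDR), capped at 1000. All thresholded lists begin at a score of 830, which corresponds to an IDR of 0.01. The ranked lists also hold the global IDR as −log10, as deposited. The signal value of each peak is the authors' own, has no stated unit, and was used to describe, rank and filter peaks, to correlate the replicates over shared peaks, and, within a list, to place steps along chromosomes and to compare X peaks with and without a motif match. The lists hold no read counts, so read depth is unknown.

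The conservative series list (1627 peaks, median width 300 bp, signal 2.07 to 1343) was the main set. Its peaks are all present in a ranked list of 105959 peaks, in which 99.5% and 99.6% of the peaks over the threshold carry member signals found in the lists of replicates 1 and 2. The other series list (1789 peaks) overlapped 84.0% of the conservative peaks. In the conservative list 63 neighbouring peaks overlap each other, and merging them leaves 1564.

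Genes, transcripts and exons were taken from Ensembl release 115, whose assembly has the chromosome names and lengths of ce11. A summit was assigned to a promoter when it lay from 1000 bp upstream to 200 bp downstream of any protein-coding 5′ end, then to an exon, an intron, another annotated gene or intergenic sequence, in that order. Shares were compared with 1000 random placements within chromosomes (permutation tests, two-sided for location and one-sided for overlap) and with ranked peaks below the threshold by Fisher's exact test. Chromosome shares were tested with exact binomial tests given lengths. Gene lists, 33 in all with 9 lists of tissue markers, were fixed before the data were examined, mostly from gene name prefixes. They were tested by Fisher's exact test against genes with a ranked summit in the promoter window. A summit counted for every gene whose window held it, so neighbouring genes can share a peak. The 22 motifs were tested by exact McNemar tests of the window within 50 bp of the summit against 1 flank drawn at random. The printed flank share is the mean of flanks centred 500 bp to either side. Fisher, binomial and McNemar tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each family. Intervals of shares are exact (Clopper-Pearson) 95% intervals. Those of gene list odds ratios are 95% intervals of the conditional odds ratio, whereas the printed odds ratio is the sample value.

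Genes were named by a rule fixed before the data were examined. It takes nhr-42 and unc-119, the gene or genes at each of the 20 strongest conservative peaks that overlap a thresholded peak of each replicate, and up to 4 bound members with the highest signal for each passing gene list and each tissue list. Summit copy number is the median count in the genome of the 24-mers within 75 bp of the summit. The step in signal along each chromosome was placed by a scan for the single position that best separates log2 signals of peaks below the threshold, with 100 permutations of the signals. Peaks that hold repeated sequence have any of these 24-mers in 2 or more copies. The copy counts, this scan and the region at the right end of II were added after the data were seen. So were the ranked peaks used as motif background, with and without GC matching, and a further motif, MEX, described under the other observations.

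Alternatives covered the other series list, the 814 strongest peaks, each replicate's own list, other promoter windows, other backgrounds, other overlap rules, and other motif windows. On simulated peaks the steps counted 300 of 300 planted promoter peaks among 1000, called 1 of 22 motifs where 1 was planted, and called 0 of 32 gene lists with nothing planted. A planted odds ratio of 12.7 was found as 17.8, with the planted value inside the interval, and a planted step at 13000000 was placed at 12996160. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.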

Results

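Chromatin immunoprecipitation followed by sequencing was performed on whole L4 larvae of Caenorhabditis elegans at an age of 50 h, from populations synchronised by starvation at the L1 stage. The animals carried a transgene in which the nuclear hormone receptor gene nhr-42 is fused to EGFP and epitope tags, and chromatin was precipitated with an antibody against GFP. Nuclear hormone receptors are ligand-regulated transcription factors, and the question addressed was where in the genome the tagged receptor is found at this stage. The series holds 1 group of 2 biological replicates, so no conditions were compared. Each replicate had its own list of peaks past the authors' threshold, 875 peaks in replicate 1 and 702 in replicate 2, and the pair had a conservative list of 1627 peaks and another list of 1789 peaks. Read depth is unknown from peak lists, and intervals on shares cover counting error only. No precipitation from animals without the tag was analysed here, so no value below has a background measured in the same way.

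The strongest peaks lay at promoters, those of several ribosomal protein genes among them, and in intergenic sequence. The highest signal value of the conservative list, 1343, belonged to a peak on II at positions 14561731 to 14561987 (build ce11), 265 bp upstream of mog-4 (WBGene00003392), which encodes a DEAH-box helicase. The signal was 830.2 in replicate 1 and 526 in replicate 2, and the summit sequence occurred in a median of 7 copies in the genome. The peak 279 bp upstream of rpl-3 (WBGene00004414), a large ribosomal subunit protein gene on III, had a signal of 937 (583 and 354 in the replicates) at positions 3867458 to 3867701, with single-copy sequence. Among the 20 strongest peaks also called in each replicate, 9 had summits in promoter windows, 10 were intergenic and 1 was intronic. Ribosomal protein promoters accounted for 4 of them, namely rpl-3, rpl-20 (642), rpl-35 (581) and rpl-15 (546).

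The other promoter peaks among these 20 lay upstream of rpa-2 (signal 795), named for replication protein A, of tasp-1 and K01G5.10, which share a peak (685), of nspc-17 (653), and of cdc-48.1 (557), which encodes an AAA ATPase of protein degradation. The peak at rpl-20 also fell in the promoter window of Y17G9B.5, and the peak at rpl-15 in that of K11H12.8. A pair of intergenic peaks on IV near K08F11.1 reached 1028 and 910.4. On X lay 7 of the 20, including an intronic summit whose nearest 5′ end was that of cest-16 (581) and intergenic summits nearest to F20B6.9 (669), W02H3.3 (642), gtr-1 (621), ZK899.6 (563) and F22H10.2 (539.6). The remaining intergenic peaks were nearest to K07D4.2 (629.8), F40E3.3 (576) and Y116A8A.150 (538). In 7 of the 20 peaks the summit sequence occurred in 2 or more genomic copies.

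The replicates shared many peaks. Of the 875 replicate 1 peaks, 442 (50.5%, 95% interval 47.1 to 53.9%) overlapped a replicate 2 peak by at least 1 bp, against 3.29 ± 1.83 (SD) in 1000 random placements (permutation test, one-sided p = 0.001, the smallest possible). In the other direction 447 of 702 peaks (63.7%) overlapped. At the ranked level, which holds weaker peaks as well, 96.6% of replicate 1 peaks overlapped some replicate 2 peak, against 35.4% in random placements. Over the 442 overlapping peaks, signal values had a Spearman rho of 0.697 and a Pearson r of 0.726 on the log2 scale (0.693 and 0.712 without the 2 strongest), a correlation across peaks, which are not independent replicates. Over the 1606 conservative peaks that overlap a ranked peak of each replicate, most of which did not pass in both, rho was lower, at 0.485 (Pearson r 0.747). Of the conservative list, 434 of 1627 peaks (26.7%) overlapped a thresholded peak of both replicates, and 740 (45.5%) overlapped one of neither. That 99.3% and 99.4% overlapped a ranked peak of replicates 1 and 2 follows largely from how the list was built. Nearly all its peaks carry member signals of both replicates' lists and were kept by their IDR. Neither this overlap nor the correlation over the 1606 peaks is thus independent support for agreement.

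**Figure D1:**
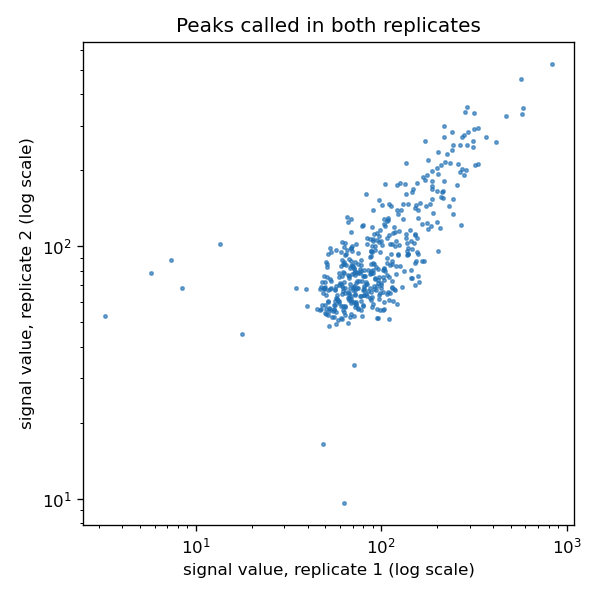
Signal value of the 442 replicate 1 peaks that overlap a replicate 2 peak, on log axes, with replicate 1 on the horizontal and replicate 2 on the vertical axis. Each point is a peak, and the strongest reaches 830.2 in replicate 1 and 526 in replicate 2.

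Peak summits were concentrated at promoters and sparse in exons. Of the 1627 conservative peaks, 742 (45.6%, 95% interval 43.2 to 48.1%) had a summit from 1000 bp upstream to 200 bp downstream of a protein-coding 5′ end, 1.76 times the 26.0% ± 1.10 (SD) found in 1000 random placements. Exons held 193 summits (11.9%, against 21.8% at random) and introns 301 (18.5%, against 27.1%). Other annotated genes, such as non-coding RNA genes and pseudogenes, held 83 (5.10%, against 3.24%) and intergenic sequence 308 (18.9%, against 21.8%). The permutation p was 0.002 before adjustment, the smallest possible, for the promoter, exon, intron and other gene classes. The adjusted permutation p was 0.0025 for these 4 and 0.00599 for intergenic sequence. Ranked peaks that did not pass the threshold had only 26.4% of summits at promoters (Fisher's exact test, odds ratio 2.33, adjusted p = 4.66e-60). Their intergenic share of 17.3% did not differ detectably from that of the passing peaks (adjusted exact p = 0.0859).

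**Figure D2:**
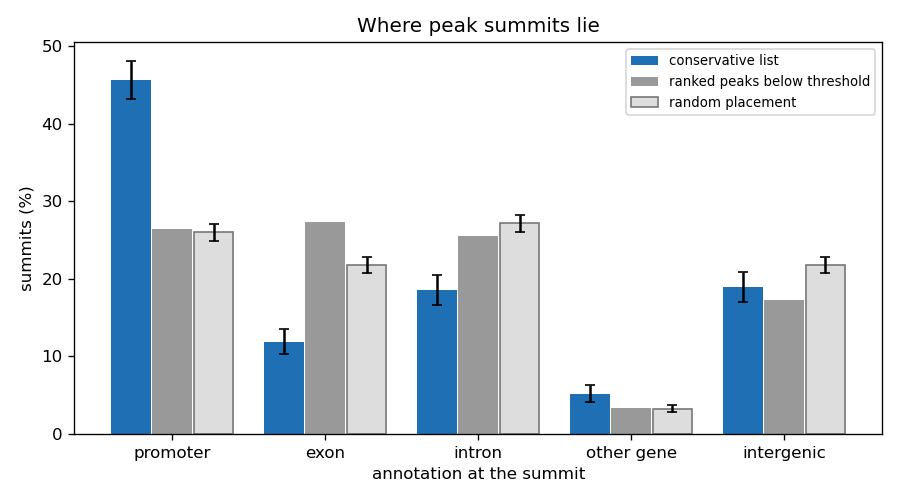
Share of summits (%, vertical axis) in each annotation class (horizontal axis) for the 1627 conservative peaks, with exact 95% intervals, for ranked peaks below the threshold, and for random placement, with 1 SD over 1000 placements. Promoters hold 45.6% of passing peaks, 26.4% of peaks below the threshold and 26.0% of random positions.

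Stronger peaks lay at promoters more often than weaker ones. Of the 407 peaks with the highest signal values, 240 (59.0%) had summits at promoters, against 149 of the 407 with the lowest (36.6%) (Fisher's exact test, odds ratio 2.49, adjusted p = 9.13e-10). Exonic summits went the other way, with 9 (2.21%) against 88 (21.6%; adjusted exact p = 2.15e-18). Ribosomal protein promoters held 18 of the strong and 2 of the weak peaks (adjusted exact p = 0.000921), and tRNA genes lay within 200 bp of 52 and 31 (adjusted p = 0.0402). Histone promoters held 5 and 1 (adjusted exact p = 0.289).

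Chromosome II held the most peaks relative to its length, and the excess lay at its right end. II carried 383 peaks (23.5% of peaks on 15.2% of the sequence, 1.54 times its share; exact binomial test, adjusted p = 1.28e-17). From position 13411280 to the end of II at 15279421, 197 peaks gave a density of 105 per Mb, against 13.9 per Mb on the rest of II and 14.5 per Mb over all sequence outside the region. Without the region, II held 0.954 times its share (exact binomial test, adjusted p = 0.615). Both replicates showed the high density, with 51.4 against 7.92 peaks per Mb in replicate 1 and 40.7 against 6.36 in replicate 2. Ranked peaks below the threshold had a higher signal to the right of a step on II. Placed separately in each replicate, the step was at 13506105 in replicate 1 (median signal 16.3 to the left and 22.2 to the right) and at 13485224 in replicate 2 (17.5 and 24.1). The region holds the peaks named here at mog-4, his-42, clec-145 and unc-52. Its bounds were chosen after the data were seen. The start is the step found in the signals of ranked peaks below the threshold in the conservative set. Raised signals of such peaks are thus how the region was chosen, not a separate finding.

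**Figure D3:**
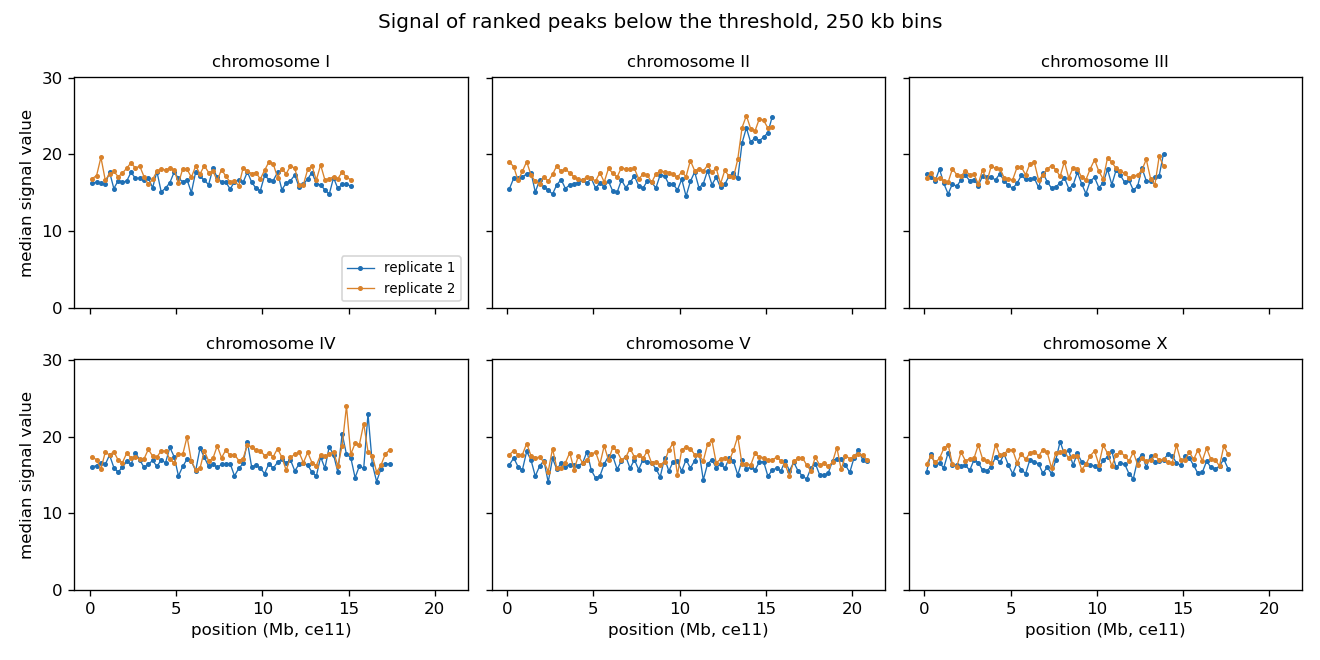
Median signal value (vertical axis) of ranked peaks below the threshold in 250 kb bins along each chromosome (horizontal axis, Mb), for replicate 1 in blue and replicate 2 in orange. Bins with fewer than 20 peaks are not drawn. On II the medians step up near the right end in both replicates, from 16.3 to 22.2 and from 17.5 to 24.1.

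X carried 332 peaks (20.4% of peaks on 17.7% of the sequence, ratio 1.15, exact binomial test, adjusted p = 0.007), whereas IV (216 peaks, ratio 0.761, adjusted p = 1.09e-05) and V (227 peaks, ratio 0.669, adjusted p = 2.37e-12) carried fewer than their length would give. I and III did not pass the test (adjusted exact p = 0.145 and 0.136). Without the right end of II the X ratio was 1.29 (adjusted exact p = 2.06e-06), and III also passed, with a ratio of 1.23 (adjusted p = 0.00138). In the replicate 1 list alone the X share was 18.9% and did not pass (adjusted exact p = 0.423). With peaks near tRNA genes left out, X held 17.2% of 1433 peaks (exact p = 0.653), or 19.9% of 1237 peaks when the right end of II was left out as well (p = 0.0887). The central part of each autosome, 33.3% of its length, held 32.4% of autosomal peaks (exact binomial p = 0.461). Without the right end of II it held 38.2%, against 34.1% of the sequence (exact p = 0.00507).

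Genes for ribosomal proteins, histones, chaperones and mitochondrial respiration were bound at their promoters far more often than other genes. In all, 884 of the 14797 protein-coding genes with any ranked summit in the promoter window had a conservative summit there (5.97%). Ribosomal protein genes were bound in 32 of 78 cases (41.0%, 95% interval 30.01 to 52.7%; Fisher's exact test, odds ratio 11.3, adjusted p = 7.41e-18). Histone genes were bound in 16 of 36 cases (44.4%, odds ratio 12.8, adjusted exact p = 8.97e-10), including his-37 (signal 373) and his-42 (194). Of the 72 histone genes on the list only these 36 had a ranked summit in the promoter window, against 78 of 80 ribosomal protein genes. The 44.4% thus leaves out histone genes without any ranked summit there. The divergent pair his-67 and his-68 share 1 peak (141). These 16 genes share 10 peaks, of which 2 have summit sequence in more than 1 copy. The histone coding regions are near-identical, so single members are uncertain. Some ribosomal protein genes also share a peak, such as rpl-24.1 with rps-10 (130) and rpl-39 with rps-30 (124). Fisher's exact test counts each gene as independent, so the p-values of these 2 lists overstate the evidence. Without the right end of II the 2 lists gave odds ratios of 11.7 and 12.5.

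Heat shock and DnaJ chaperone genes were bound in 11 of 40 cases (27.5%, odds ratio 6.03, adjusted exact p = 0.000125). They included hsp-3 (signal 304), a chaperone of the endoplasmic reticulum, and the mitochondrial chaperonin gene hsp-60 (292). Others were dnj-13 (285) and the cytosolic chaperone gene hsp-90 (202). The peaks at hsp-60, dnj-13 and hsp-90 also fell in the promoter windows of Y22D7AL.10, F54D5.9 and C47E8.4. The hsp-90 summit lies inside the gene and was assigned through an annotated 5′ end within it. Genes of mitochondrial respiration were bound in 9 of 36 cases (25%, odds ratio 5.29, adjusted exact p = 0.00134). Among these were the cytochrome c oxidase subunit genes cox-5A (signal 400.1), cox-6A (229.6) and cox-5B (229.4), and atp-1 (279), the ATP synthase alpha subunit gene. The atp-1 peak also fell in the promoter window of mcrs-1. When peaks were assigned to the nearest 5′ end instead, neither list passed (odds ratios 2.07 and 2.79, adjusted exact p = 0.247 and 0.0809).

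Large gene families of sensory, cuticle and defence functions were bound less often than other genes. Chemoreceptor genes were bound in 8 of 702 cases (1.14%, odds ratio 0.174, adjusted exact p = 9.08e-10), with sre-23 (signal 194), sri-5 (164), srh-269 (149.9) and srh-2 (111) the strongest. The peak at sri-5 also fell in the promoter window of rsr-1. The srh-2 summit lies inside the gene and was assigned through an annotated 5′ end within it. Cuticle collagens were bound in 1 of 138 cases, col-185 (101), with an odds ratio of 0.114 and an adjusted exact p of 0.0185. Genes of innate immunity were bound in 6 of 263 cases (2.28%, odds ratio 0.363, adjusted exact p = 0.0377), the strongest being clec-57 (106), fipr-17 (105), clec-126 (79.2) and clec-145 (78.7). The peaks at clec-57 and fipr-17 also fell in the promoter windows of srz-97 and Y48A6B.3. The collagen call was lost in each replicate's own list (adjusted exact p = 0.536 and 0.163), among the stronger peaks (0.195), with the nearest 5′ end (0.701) and with a wider promoter window (0.11). The immunity call was lost in the replicate 1 list (adjusted exact p = 0.409).

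For nuclear hormone receptor genes themselves no difference from other genes was detected, with a bound promoter in 11 of 215 cases (5.12%, odds ratio 0.847, 95% interval 0.414 to 1.56, adjusted exact p = 0.909). None of the 9 lists of tissue markers passed. Bound members were cpr-6 (signal 77.5) of 17 intestinal markers and unc-52 (103), the perlecan gene, of 26 body muscle markers. Of 23 germline markers, syp-4 (98.7) and cgh-1 (77.5) were bound. The unc-52 summit lies inside the gene and at the right end of II, without which 0 of 25 body muscle markers were bound. The syp-4 summit sequence has a median of 7.5 genomic copies, and its peak also fell in the promoter window of H27M09.5. No marker of hypodermis, neurons, pharynx, ciliated neurons, the excretory system or glia was bound, of 23, 21, 22, 35, 16 and 8 in the background. For the 35 ciliated neuron markers this still allows a share of up to 10.003% (exact 95% interval), above the 5.97% of all genes, so a depletion was not detectable for these lists.

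The other lists that did not pass were, with bound and background counts, vacuolar ATPase (4 of 19, adjusted exact p = 0.0875), proteasome (4 of 30, 0.304), heterochronic genes (2 of 14, 0.514), tRNA synthetases (2 of 26, 0.815), dauer genes (2 of 25, 0.815) and bHLH factors (1 of 21, 1). Some of these calls depended on how peaks were assigned to genes. With the nearest 5′ end, heterochronic genes (odds ratio 13.5, against 2.63 with the promoter window; adjusted exact p = 0.000189) and vacuolar ATPase genes (4.95, against 4.21; p = 0.0178) passed. Vacuolar ATPase genes also passed with all protein-coding genes as background (5.42, adjusted exact p = 0.0469) and without peaks that hold repeated sequence (5.48, p = 0.0428), and proteasome genes with the wider promoter window (3.52, against 2.43; p = 0.0327). Lower shares that did not pass were found for F-box and MATH genes (8 of 298, adjusted exact p = 0.053), sperm proteins (0 of 68, 0.113), neuropeptides (2 of 96, 0.354), detoxification (6 of 162, 0.647), lipid metabolism (3 of 84, 0.806) and homeobox genes (2 of 66, 0.761). The same held for hedgehog-related genes (2 of 67, 0.761), molting (1 of 42, 0.811), GATA, forkhead and T-box factors (0 of 35, 0.593) and Wnt genes (0 of 14, 1). Of these, F-box and MATH genes (odds ratio 0.429) passed in the other series list (0.445, adjusted exact p = 0.049), with the nearest 5′ end (0.203, p = 9.08e-06) and with the wider window (0.352, p = 0.00119).

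**Figure D4:**
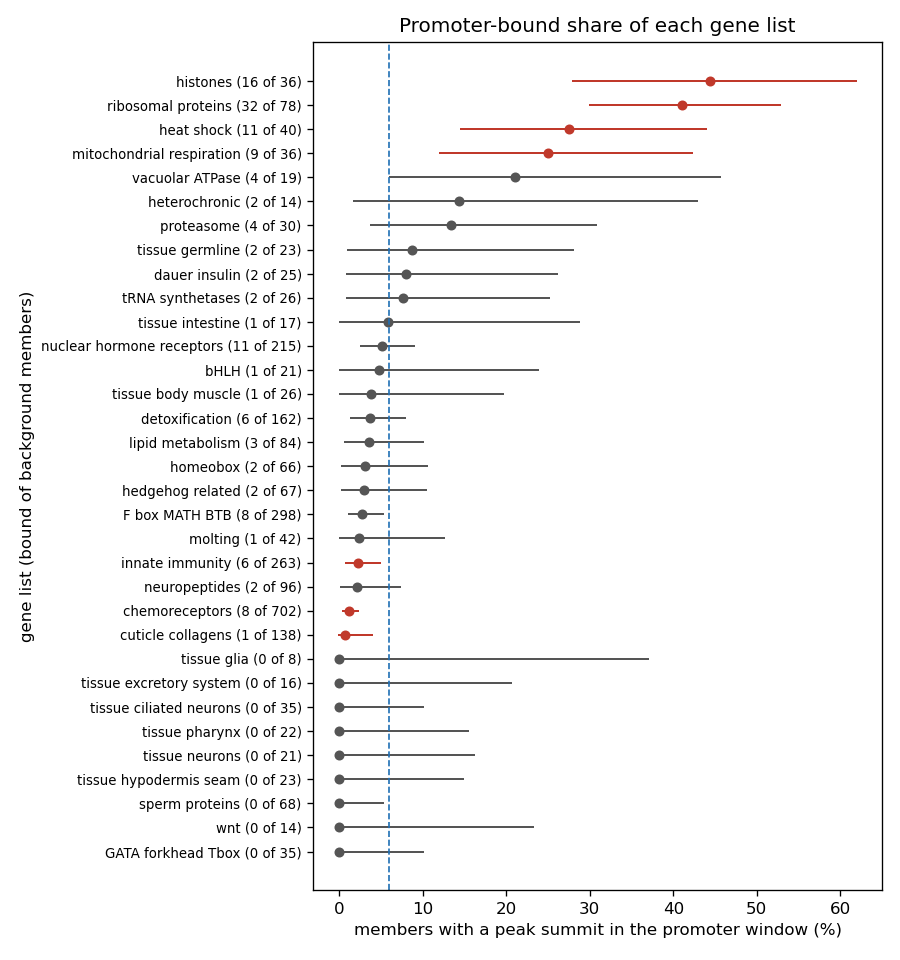
Share of each gene list's background members with a conservative summit in the promoter window (horizontal axis, %), with exact 95% intervals. Lists with an adjusted p under 0.05 are in red, and the dashed line marks the 5.97% of all background genes. Histones reach 44.4% and ribosomal proteins 41.0%, while chemoreceptors are at 1.14%.

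Genes for small non-coding RNAs were frequent peak sites. Within 200 bp of a tRNA gene lay 194 of 1627 summits (11.9%), against 4.59 ± 2.18 (SD) in random placements and 0.300% of ranked peaks below the threshold. Summits near snoRNA genes numbered 72 (3.06 ± 1.71 at random), those near snRNA genes 28 (0.965 ± 0.993) and those near miRNA genes 9 (2.13 ± 1.42). All 4 had a permutation p of 0.002 before adjustment, the smallest possible, and an adjusted permutation p of 0.0025. No summit lay near an rRNA gene, where 0.222 were found at random (permutation p = 1). Of 612 annotated tRNA genes, 211 (34.5%) had a summit within 200 bp. On X, 25.9% of peaks were near a tRNA gene, against 8.34% on the autosomes. X holds 45.1% of the tRNA genes and 44.3% of the 194 peaks near them.

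Summit sequence was rich in G and C, and no enrichment of the receptor half-site was detected. G and C made up 48.6% of bases within 50 bp of summits, against 36.8% in flanks 500 bp away and 39.7% at ranked peaks below the threshold. The half-site AGGTCA, to which many nuclear hormone receptors bind, was present in 2.89% of summit windows and 2.49% of flanks (exact McNemar test against 1 flank per peak, adjusted p = 1). Its variant AGTTCA was in 4.12% and 6.67% (adjusted exact p = 0.0628), and passed as less frequent at summits with windows of 100 bp to either side (adjusted p = 0.00482), with flanks at 300 bp (0.00605) and without the right end of II (0.0208). The forkhead site TRTTTAC (2.27% and 3.53%, ratio 0.643, adjusted exact p = 0.244) also passed as less frequent with windows of 100 bp to either side (ratio 0.679, adjusted p = 0.0315). The sequence GAGAGA was in 15.4% of summit windows against 5.72% of flanks (ratio 2.69, adjusted exact p = 6.99e-21), CTGCGTC in 5.72% against 1.14% (ratio 5.03, adjusted p = 2.55e-10) and the GC box GGCGGG in 7.19% against 1.84% (ratio 3.9, adjusted p = 2.25e-12). The E-boxes CAGCTG and CACGTG had ratios of 1.79 and 1.81 (adjusted exact p = 0.00123 and 0.0159), but CAGCTG did not pass in the replicate 2 list (adjusted p = 0.113), nor CACGTG in the replicate 1 list (0.325).

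Runs of T (ratio 0.47, adjusted exact p = 9.39e-35), TATAAA (0.355, adjusted p = 5.02e-13), the homeodomain site TAATTA (0.35, adjusted p = 7.04e-06) and the GATA factor sites WGATAR (0.716, adjusted p = 0.00123) and TGATAA (0.66, adjusted p = 0.0296) were less frequent at summits than in flanks. TGATAA did not pass in the other series list (adjusted exact p = 0.417) or the replicate 1 list (0.0518). Many of the motif calls depended on the background. Set against 1627 ranked peaks below the threshold with matched G and C content, GAGAGA (ratio 1.85, Fisher's exact test, adjusted p = 1.04e-08) and CTGCGTC (ratio 2.91, adjusted p = 2.65e-07) still passed. The GC box (1.27, adjusted exact p = 0.378), both E-boxes (0.792 and 1.06), T runs (1.03), TATAAA (1.15), TAATTA (1.32), AGTTCA (0.827) and the GATA sites (1.22 and 1.39) did not. The matching did not cover location. Of all ranked peaks below the threshold 26.4% lay at promoters and 0.300% near tRNA genes, against 45.6% and 11.9% of conservative peaks. Whether GAGAGA and CTGCGTC mark such locations rather than the peaks was not tested. Against 1 random draw of 1627 such peaks without the matching, the GC box (3.44, adjusted exact p = 1.31e-11), T runs (0.594, adjusted p = 2.83e-16) and TATAAA (0.55, adjusted p = 0.000599) still passed, as did CACGTG (1.66, adjusted p = 0.0345) and TAATTA (0.521, adjusted p = 0.0321) by less. CAGCTG (1.49, adjusted exact p = 0.136), WGATAR (0.897, 0.377) and TGATAA (0.767, 0.127) did not, so their calls ended without the matching. Of 2080 6-mers, 618 were more frequent at summits and 380 less frequent, and 468 of the former had 4 or more G or C bases. The lowest p among the enriched belonged to GCGCAC (9.47% against 1.63%, adjusted exact p = 6.3e-24) and among the depleted to AAAATT (17.5% against 40.9%, adjusted p = 1.15e-51).

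No peak was called around the tagged gene itself. No summit of any list lay within 20 kb of nhr-42 (WBGene00003632, V, positions 6998819 to 7000651), although in the ranked list of the conservative set a random protein-coding gene had a median of 46 summits within that distance and only 5 of 1000 random genes had none. The nearest ranked summits of the conservative set were at 6962116 and 7035899, a gap of 73.8 kb, the 11th longest of 105953 gaps (median 607 bp). The gap was 76.9 kb in replicate 1 and 65.3 kb in replicate 2. Coverage of a control was not analysed, so the lack of called peaks does not show a lack of binding there. At unc-119 (WBGene00006843, III, positions 10902641 to 10908935), the rescue gene carried by the transgene, 38 ranked summits lay within 20 kb (one-sided permutation test for an excess, p = 0.685) and no conservative summit did.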

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

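All tests in this part were chosen after the result was seen. In the ranked list of the conservative set, 66 peaks reached the score of the threshold and are absent from the conservative list, which lies outside what the report compares. They include the strongest peak of that ranked list, on X at positions 15810942 to 15811197, with a signal of 3332 (1583 in replicate 1 and 1873 in replicate 2), against 1343 for the strongest listed peak. The summit sequence occurs in 2 or more genomic copies for 61 of the 66 (92.4%), against 9.90% of the conservative peaks, and 57 of the 66 are intergenic. Similar sets of 39 and 54 peaks are absent from the thresholded lists of replicates 1 and 2. The step that removed them is not given in the sources used here, and no explanation was tested.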

How the results depend on the processing

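The leaving out of the right end of II, the merging of overlapping peaks, the leaving out of peaks near non-coding genes or with repeated sequence and the backgrounds of ranked peaks with and without GC matching were chosen after seeing the data. Of 604 values under alternative settings, 504 kept their direction and side of the threshold, 18 lost the call, 12 gained it, 66 changed direction and 4 counts or shares moved. The promoter share passed under every alternative tried (45.6 to 60.7%), as did the ribosomal protein (odds ratio 4.37 to 14.9), histone (4.29 to 12.8) and chemoreceptor lists (0.0964 to 0.261). No paired analysis was possible because there is 1 group.

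The X share was 18.9 to 22.1% in the lists of single replicates, and did not pass in replicate 1 alone. Promoter-bound genes numbered 421 to 619 in those lists and 573 among the 814 strongest peaks, which are fewer by construction. The replicate overlap was 44.5% with 50% of each peak required and 56.6% between the upper 50% of each list by signal.

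The changes of direction in gene lists were all in lists that did not pass. Odds ratios in the other series list were 1.14 for nuclear hormone receptors, 2.39 for bHLH factors and 1.68 for intestine. Among the 814 strongest peaks they were 1.21 for nuclear hormone receptors, 0 for dauer genes, 0.856 for the proteasome and 0.993 for tRNA synthetases. In single replicates they ranged from 1.01 to 1.12 for nuclear hormone receptors, 0 to 0.777 for dauer genes, 0.687 to 1.14 for the proteasome, 0.851 to 1.24 for tRNA synthetases, 0 to 1.28 for intestine and 0 to 1.5 for germline. Without the right end of II they were 0.727 for dauer genes and 1.04 for intestine. With the nearest 5′ end they were 1.08 for nuclear hormone receptors, 3.3 for bHLH factors, 1.67 for lipid metabolism, 1.21 for intestine, 1.65 for hypodermis, 1.05 for neurons, 0.426 for germline and 1.53 for the excretory system. With the wider window they were 1.57 for bHLH factors, 1.11 for lipid metabolism, 0.962 for dauer genes and for germline, 0.829 for tRNA synthetases, 1.34 for intestine, 1.09 for neurons and 1.002 for body muscle. Intestine was at 1.03 with all protein-coding genes as background, and at 1.1 without peaks near non-coding genes, where germline was at 0.8003. Without peaks that hold repeated sequence they were 1.02 for bHLH factors, 0 for tRNA synthetases, 1.28 for intestine and 0.929 for germline.

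Motif ratios in the other series list were 0.978 for AGGTCA and 2 for the direct repeat DR1. Among the 814 strongest peaks they were 0.857 for AGGTCA and 0.706 for the bZIP palindrome. In single replicates they ranged from 0.909 to 1.3 for AGGTCA, 0 to 0 for the HNF4-like site, 0 to 2 for the T-box and 0.545 to 1.17 for the bZIP palindrome. The HNF4-like site was at 0.667 with windows of 100 bp to either side, and AP-1 and the BLMP-1-like site were at 0.938 and 1.25 with flanks at 300 bp. Against GC-matched peaks, ratios were 1.27 for AAGTCA, 1.22 for WGATAR, 1.39 for TGATAA, 0.792 for CAGCTG, 1.37 for forkhead, 1.32 for TAATTA, 0.5 for HNF4-like, 0.64 for bZIP, 1.03 for T runs, 2 for BLMP-1-like and 1.15 for TATAAA. Against as many ranked peaks without GC matching, ratios were 1.23 for forkhead, 0.25 for HNF4-like and 2 for BLMP-1-like. T runs, TATAAA and TAATTA kept their direction and call against the unmatched peaks and lost both when G and C content was matched as well. For the other changes the cause was not tested. Read depth is unknown, so its limits cannot be given.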

Other observations

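The tests of the promoter share at the right end of II, of signal at the motif matches on X and of repeated sequence at histone peaks were chosen after the result was seen. A set of strong peaks on X carried near matches to a motif that marks recruitment sites of the dosage compensation complex, which lowers X expression in hermaphrodites. The motif, MEX, has the sequence TCGCGCAGGGAG, taken from general knowledge of the field. It was not among the motifs tested in the results above and was added after the data were seen. The p-values and counts for its matches are thus not those of a planned test. A match of at least 10 of its 12 bases within 100 bp of the summit was found in 32 of 332 X peaks (9.64%) and in 13 of 1295 autosomal peaks (1.00%; Fisher's exact test, odds ratio 10.5, p = 1.25e-13). Exact matches on X numbered 2, so most of the 32 hold mismatches. The matching X peaks had a median signal of 185, against 99.5 for the other X peaks, and 8 of the 32 lay in promoter windows. Their mean log2 signal was higher by 0.93 (permutation test, two-sided p = 2e-05, the smallest possible). Of the 100 strongest conservative peaks, 25 were on X and 14 of these carried a match, as did 6 of the 7 X peaks among the 20 strongest called in each replicate.

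For these X matches, 0 of 100 column-shuffled motifs reached the count of 32 (the highest gave 14), which argues against base composition. Among ranked X peaks below the threshold only 89 of 18757 (0.474%) matched. The odds ratio between passing and other X peaks was 22.4, with a lower bound of 14.2, which argues against a high frequency of the motif on X as such. A hypothesis is that sites of dosage compensation binding may collect signal in this precipitation. Whether that depends on the tagged receptor or would appear with any antibody against GFP stays open, since no precipitation without the tag was analysed here, and no biological explanation was tested.

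The dense region at the right end of II, 1.87 Mb or 1.86% of the genome, held 197 of 1627 peaks. Peaks below the threshold had raised signals there in promoters, exons, introns and intergenic sequence alike. The rises were 0.32 to 0.52 on the log2 scale over both replicates, and the lowest of the 8 was 0.612 of the highest. The start of the region was placed by such a rise, so only its evenness over classes adds information. That evenness was loose, from 1.25-fold (intergenic, replicate 1) to 1.44-fold (exons, replicate 2). It does not tell a larger copy number from another broad rise over the region. Passing peaks in the region lay at promoters less often than elsewhere (33.5% against 47.3%, Fisher's exact test, odds ratio 0.562, p = 0.000318), which argues against an excess confined to promoters. Promoter peaks were dense there as well, with 66 in this 1.86% of the genome and 676 elsewhere. More binding at the region's promoters is thus not excluded. The promoter share of peaks below the threshold in the region was not tested. A candidate explanation is a larger copy number of this region in the animals than in a control, if 1 was used for peak calling. A lower coverage of such a control there would look the same, and no biological explanation was tested.

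For the peaks at ribosomal protein and histone genes, the tables argue against several technical explanations. Without peaks near non-coding RNA genes, 31 of 78 ribosomal protein genes were still bound (Fisher's exact test, odds ratio 12.05, adjusted p = 3.87e-18). Without the right end of II, the higher adjusted p of both lists was 9.84e-09. With the 521 peaks left out that have any 24-mer within 75 bp of the summit in 2 or more genomic copies, 12 of 36 histone genes were still bound (odds ratio 10.4, adjusted exact p = 4.71e-07), which argues against reads shared between gene copies as the whole cause. A part in the peaks left out stays open. Genes that share a peak were counted separately in these tests, so their p-values overstate the evidence. It stays open whether highly transcribed genes, tRNA genes included, may collect signal in any precipitation of this kind.

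The empty stretch around nhr-42 was shared by both replicates, and only 4 of 1000 random genes had as few ranked summits within 20 kb in each replicate's list. Whether binding is absent there or peaks were not called for a reason such as high coverage of a control stays open, and no explanation was tested. Nuclear hormone receptor genes bound at their promoters included nhr-47 (signal 199), nhr-178 (185), nhr-68 (159) and nhr-238 (155), named after their values were seen. The peak at nhr-47 also fell in the promoter window of dnj-19, and the peak at nhr-68 in that of H12C20.7. On chromosomes other than II, the largest step in median signal in a replicate's list was 0.10 on the log2 scale, on V in replicate 1, against 0.44 and 0.46 on II. In the ranked list of the conservative set the step was -0.22 on X (scan statistic 2.66, highest permutation 4.14) and 0.59 on II. Small steps on I and III in that list, and on III and V in replicate 2, also exceeded the highest of 100 permutations.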
